A study of Homo sapiens with 9 samples.

How the data were processed

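ATAC-seq was performed on 9 libraries of the VCaP prostate cancer line and its enzalutamide-resistant derivative VCaP16. The labels' bulk protocol has cells crosslinked with 1% formaldehyde for 10 minutes before tagmentation with Tn5; the same protocol text describes a single-cell ATAC preparation without saying which of these a peak list comes from, and the lists were treated as bulk libraries. The submitters' processing notes name hg19, BWA 0.7.15-r1140, MACS2 2.2.7.1 and HOMER 3.12, without their roles or settings, and how reads were filtered or shifted for Tn5 is not given in the sources used here. The authors deposited one peak list per library, so peaks were called per library and replicates were not pooled. Each list gives the chromosome, start, end, name and score of a peak. The deposited score was taken as the −log10 of a p-value or q-value, since it never fell below 2 in any list, which would be a limit of 0.01; the sources used here do not say which of these it is. Peak numbers ran without a gap from 1 to the length of each list.

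A peak caller's score moves with the depth of its library, and so does the number of peaks called. The lists hold no read counts, pileup or fold, so the depth per library is unknown and no correction for depth could be made; lists of equal length were used in its place. Scores were used only to rank or filter peaks within a list, and lists were compared by overlap. Coordinates are those of the authors' lists on hg19, written from 1. Peaks on chromosomes 1 to 22 and X were kept.

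Peaks of all libraries that overlapped by at least 1 bp were merged, and regions called in at least 2 of 3 libraries of at least 1 group formed the consensus. A region counted as called in a library if a peak of that library overlapped it by at least 1 bp. Regions called in 3 of 3 libraries of one group and 0 of 3 of another were counted in both directions. These counts were set beside those from every other split of the same libraries, and beside 100 simulations in which each region kept its rate of calling over the 9 libraries and each library its total yield, with no group effect. Peak number, covered length, peak width and the share of consensus regions called were compared with two-sided exact permutation tests: 280 splits for 3 groups of 3, 84 splits for 3 against 6 and 3 against 3 libraries for pairs of groups, where the smallest p values are 0.00357, 0.0119 and 0.1. Similarity of libraries was the Jaccard index by bases. Single regions were tested only for VCaP16 against the 6 VCaP libraries, with Fisher's exact test and Benjamini-Hochberg adjustment. The distribution over chromosomes was tested with a chi-square test over regions, and the share of each library's peaks per chromosome with the exact permutation test of 3 against 6.

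The named regions are, for each direction of each comparison, the 10 with the best median rank of the score within the libraries that call them. This rule, the tests, the groups and the settings listed next as planned were fixed before the data were examined. Added after were the chi-square tests among variable regions and between directions, the comparison of 5 Mb stretches, the clusters per Mb, the choices of 3 libraries as controls and the simulations without group effects. The counts over other splits of the libraries were planned, and what they would show was written down only after they were seen. On simulated lists built from the 66108 consensus regions, with 200 regions set to the VCaP16-only pattern and 200 to the VCaP_DMSO-only pattern, and with region edges moved inward at random, the counting step recovered 100% of each. In all it counted 493 and 466 regions, the rest from regions drawn without a pattern. The seeded calls were 3 of 3 against 0 of 3. Since edges moved only inward, peaks of a region always overlapped and neighbouring regions could not merge. Full recovery was thus fixed in advance. It checks that the counting runs as meant, not how real peaks merge or the power to find weaker differences.

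Planned other settings were a minimum score of 5, the same number of best peaks from every list, an overlap of at least 50% of the region, a call in at least 2 of 3 libraries, all merged regions, leaving out each library in turn and permutation within replicate numbers. Added after seeing the data were windows about peak midpoints, a minimum score of 5 or 10 in the calling libraries only, and leaving out both of the longest lists. The midpoint windows were 250 bp wide for merging and calling, and the merged regions were then written as 500 bp. The planned windows about peak summits were not run because the lists hold no summits. The planned comparisons of promoter shares, gene lists and motifs, and the planned estimate of depth, were not run: no hg19 genome or annotation was used here, and the gene table at hand is on another build, from which no coordinates were taken. Whether the named regions lie in repeats or duplicated sequence was therefore not checked. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.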

Results

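Accessible chromatin was mapped by ATAC-seq in 9 libraries from VCaP cells, a human prostate cancer line. In this assay the transposase Tn5 inserts sequencing adapters into open DNA, and a peak marks a place where insertions pile up. The libraries fell into 3 groups of 3. VCaP_DMSO held VCaP cells given the solvent, VCaP_ENZ held VCaP cells treated with 10 µM enzalutamide, a drug used against prostate cancer, for 96 h, and VCaP16 held an enzalutamide-resistant VCaP line kept in 16 µM of the drug. The comparisons asked which chromatin was open after short exposure to the drug and which was open in the resistant line, each against the solvent control and against each other. No VCaP16 library was without the drug, so against VCaP_DMSO the line and the drug cannot be told apart. The drug groups also differ in dose. The deposited lists gave each peak's position on hg19 and the authors' score, and no read counts, so the depth of each library is unknown. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No annotation of hg19 was used here, so regions are given by coordinates and none is assigned to a gene, exon or promoter.

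On chromosomes 1 to 22 and X, the VCaP_DMSO libraries had 57677, 54757 and 53799 peaks, the VCaP_ENZ libraries 54033, 61744 and 53646, and the VCaP16 libraries 57894, 57315 and 68921. The means were 55411 ± 2020 in VCaP_DMSO, 56474 ± 4568 in VCaP_ENZ and 61377 ± 6540 in VCaP16 (SD, n = 3 each). Peaks covered 28.6 ± 2.03 Mb, 28.3 ± 3.68 Mb and 31.3 ± 4.47 Mb of sequence in the same order, with mean peak widths of 516 ± 18.5 bp, 500 ± 23.7 bp and 508 ± 20.4 bp. Neither the peak number (p = 0.361) nor the covered length (p = 0.589) differed between the 3 groups beyond the spread of replicates in two-sided exact permutation tests over 280 splits. VCaP16 had 5434 more peaks on average than the 6 VCaP libraries, with an exact permutation p of 0.131 over 84 splits. The exact permutation p was 0.0357, with a difference of 6594 peaks, without VCaP_ENZ replicate 2, and the difference was 1662 peaks (p = 0.536) without VCaP16 replicate 3, the longest list. Against VCaP_DMSO alone the difference was 5966 peaks for VCaP16 (exact permutation p = 0.2) and 1063 for VCaP_ENZ (exact permutation p = 0.9). These tests of 3 against 3 libraries cannot give a p below 0.1. The VCaP16 difference was 2194 without VCaP16 replicate 3, and the VCaP_ENZ difference turned to -1572 without VCaP_ENZ replicate 2.

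**Figure D1:**
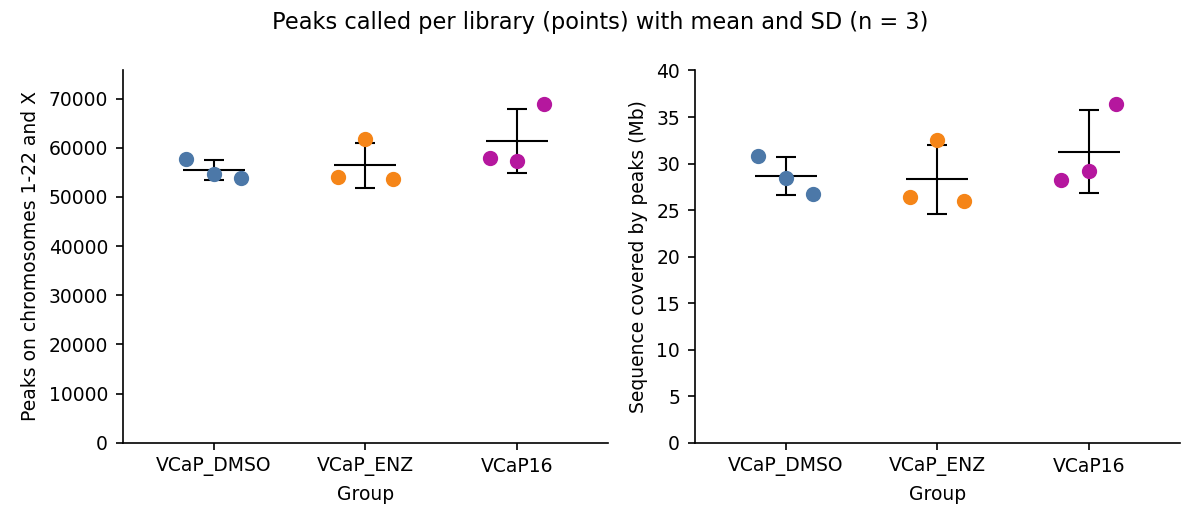
Number of peaks (left panel) and sequence covered by peaks in Mb (right panel) in each library, by group; points are libraries, and the bars show the group mean and SD (n = 3). The groups overlap, and VCaP16 replicate 3, with 68921 peaks over 36.4 Mb, lies above the other libraries in both panels.

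Much of the open chromatin was shared. Peaks of all libraries merged into 94773 regions, of which 66108 were called in at least 2 of 3 libraries of some group, and 33033 of these consensus regions (50.0%) were called in all 9 libraries. Of the consensus regions, 76.7% ± 2.4 were called per VCaP_DMSO library, 77.7% ± 4.84 per VCaP_ENZ library and 82.9% ± 5.41 per VCaP16 library (SD, n = 3 each). The higher share in VCaP16 than in the 6 VCaP libraries had an exact permutation p of 0.0952. Libraries of one group shared slightly more called sequence than libraries of different groups: the Jaccard index, the shared bases divided by the bases called in either library, averaged 0.604 over the 9 pairs within groups and 0.589 over the 27 pairs between groups. The difference of 0.0151 had an exact permutation p of 0.00357, the smallest that 280 splits can give, and the next split reached 0.0149. Within groups the mean was 0.612 in VCaP_DMSO, 0.602 in VCaP_ENZ and 0.598 in VCaP16. By pair of groups, VCaP_DMSO and VCaP_ENZ were closest (mean 0.597), followed by VCaP_ENZ and VCaP16 (0.585) and VCaP_DMSO and VCaP16 (0.584). The VCaP16 libraries were thus hardly more alike than libraries of VCaP_DMSO and VCaP_ENZ. The most similar pair of libraries lay across groups, VCaP_DMSO replicate 1 and VCaP_ENZ replicate 2, at 0.629.

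Short exposure to enzalutamide was compared with the solvent. Of the consensus regions, 619 (0.936%) were called in all 3 VCaP_ENZ libraries and in no VCaP_DMSO library, and 528 (0.799%) showed the reverse. The best-ranked VCaP_ENZ region lay at chromosome 20, 44258220 to 44258693, with a median score of 18.9, and the next at chromosome 7, 120195064 to 120195473, with 19.2; both were also called in all 3 VCaP16 libraries. The 10 best-ranked VCaP_ENZ regions had median scores of 14.0 to 19.2, and 5 of them were called in every VCaP16 library and 2 in none. With an overlap of at least 50% of the region only 4 of the 10 kept the pattern, and the 2 regions named did not. The best-ranked region called with the solvent and not with the drug lay at chromosome 8, 104992016 to 104992564 (median score 29.1), and was called in all 3 VCaP16 libraries as well; it lost the pattern with the 50% overlap, which 7 of the 10 best-ranked regions of this direction kept. Regions at chromosome X, 61881460 to 61881875 (median score 30.1), and chromosome 16, 2438758 to 2439196 (27.7), were called in every VCaP_DMSO library, in no VCaP_ENZ library and in 1 VCaP16 library. Regions at chromosome 3, 161304499 to 161305074, and chromosome 5, 57994823 to 57995615, were called in all 3 VCaP_DMSO libraries and in none of the other 6. The 10 best-ranked regions of this direction had median scores of 18.5 to 30.1. No region was tested singly, since 3 against 3 libraries cannot give a p below 0.1; the highest count in the other splits of these 6 libraries was 579. With the same number of best peaks from each list the balance turned, to 544 regions with the drug and 604 with the solvent, as it did with an overlap of at least 50% of the region, to 624 and 646, and with a score of at least 10 in the calling libraries, to 23 and 52. It also turned to 1010 and 1341 without VCaP_ENZ replicate 2, to 1067 and 1161 without VCaP_DMSO replicate 2 and to 1021 and 1181 without VCaP_DMSO replicate 3. The counts were 1451 and 825 without VCaP_ENZ replicate 1 and 1528 and 826 without VCaP_ENZ replicate 3.

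The resistant line was compared with solvent-treated VCaP cells. In all, 1543 regions (2.33%) were called in all 3 VCaP16 libraries and in no VCaP_DMSO library, against 504 (0.762%) in the reverse direction, a ratio of 3.06. The best-ranked VCaP16 region lay at chromosome 22, 24170860 to 24171399, where the scores ran from 40.7 to 47.8. Its median position was 9.69% from the top among the consensus regions called in each VCaP16 library. It was followed by chromosome 17, 219344 to 219741 (median score 34.2), chromosome 20, 39988098 to 39988724 (36.1), and chromosome 5, 132975861 to 132976445 (36.0). The first 3 of these were called in 1 VCaP_ENZ library and the last in 2. Regions at chromosome 11, 71075193 to 71075791, chromosome 14, 60161867 to 60162313, and chromosome 20, 49338320 to 49338763, were called in all 3 VCaP_ENZ libraries too. In the reverse direction, the best-ranked regions lay at chromosome 22, 18879972 to 18880465, with scores of 46.4 to 47.1, and at chromosome 15, 80996993 to 80997617, with scores of 41.4 to 47.0. The first was called in 2 VCaP_ENZ libraries and the second in all 3, and neither in any VCaP16 library. Regions at chromosome 7, 56441047 to 56441389 (median score 39.9), and chromosome 10, 106128199 to 106128584 (36.9), were likewise called in all 6 VCaP libraries and in no VCaP16 library. With the 50% overlap 8 of the 10 best-ranked VCaP16 regions and 9 of the 10 VCaP_DMSO regions kept the pattern, including all those named. Most regions of both directions were weak. Among the consensus regions called in a library, their median position was 77.7% from the top for VCaP16 and 81.2% for VCaP_DMSO. The highest count in the other splits of the 6 libraries was 623, and 3 against 3 libraries allow no p below 0.1. With lists of equal length the counts were 1088 and 877, a ratio of 1.24, and without VCaP16 replicate 3 they were 2063 and 1219, a ratio of 1.69. The ratio was 2.02 without VCaP_DMSO replicate 3 and 4.31 without VCaP16 replicate 1, the lowest and highest with other single libraries left out.

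**Figure D2:**
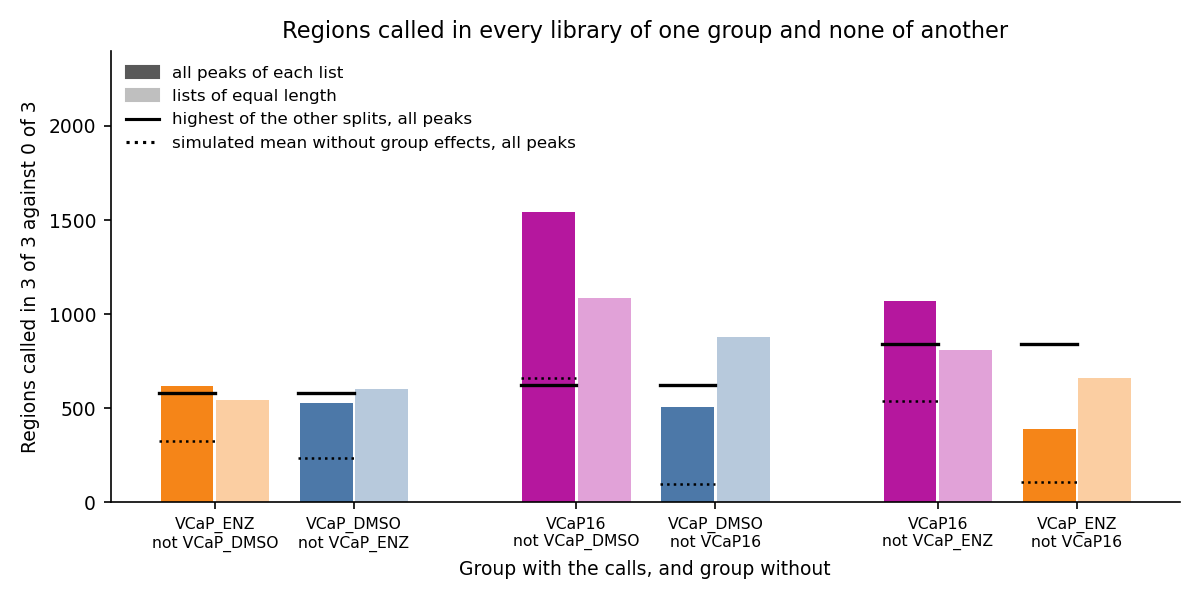
Regions called in all 3 libraries of the upper-named group and in none of the lower-named group; full bars use all peaks, pale bars the same number of best peaks from each list, solid lines the highest count in the other splits of the same 6 libraries and dotted lines the mean of simulated libraries without group effects. The VCaP16 bar against VCaP_DMSO reaches 1543 with all peaks and 1088 with lists of equal length, while its reverse goes from 504 to 877.

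Both groups exposed to the drug were compared with each other. There were 1068 regions (1.62%) called in all VCaP16 and no VCaP_ENZ libraries and 389 (0.588%) in the reverse direction, a ratio of 2.75. The best-ranked VCaP16 region lay at chromosome 8, 99414739 to 99415214, with scores of 21.9 to 31.1, and was called in no VCaP_DMSO library either. The region at chromosome 9, 44419926 to 44420255 (median score 28.5), was called in 1 VCaP_DMSO library and that at chromosome 13, 52810198 to 52810826 (24.0), in 2. Of the 10 best-ranked regions, 5 were called in no VCaP_DMSO library. In the reverse direction the region at chromosome 7, 56441047 to 56441389, ranked first, with a median score of 22.9 in VCaP_ENZ, and the region at chromosome 21, 9825486 to 9826316 (19.7), came next; both were called in all 6 VCaP libraries. Regions at chromosome 19, 23663977 to 23664220 (17.7), and chromosome 7, 81039820 to 81040334 (14.0), were called in the 3 VCaP_ENZ libraries and nowhere else. In each direction 5 of the 10 best-ranked regions kept the pattern with the 50% overlap; of those named, the regions on chromosomes 13 and 21 and that at chromosome 7, 81039820, did not. The highest count in the other splits was 841. With lists of equal length the counts were 809 and 660, a ratio of 1.23, and without VCaP16 replicate 3 they were 1554 and 1122, a ratio of 1.39. The ratio was 1.54 without VCaP_ENZ replicate 3 and 3.93 without VCaP16 replicate 1, the lowest and highest with other single libraries left out, and 16.4 (115 and 7) with a score of at least 10 in the calling libraries.

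Against all 6 VCaP libraries, 520 regions (0.787%) were called in every VCaP16 library and in no VCaP library, and 83 (0.126%) in every VCaP library and in no VCaP16 library. The highest counts in the other splits of 3 against 6 libraries were 239 and 214. The 214 came from VCaP_DMSO against the 6 libraries given the drug, which is a real grouping, and the remaining splits reached at most 151. The first count thus lay above and the second below what other splits reached. After the region on chromosome 8 named above, the VCaP16 regions ranked best were those at chromosome 20, 48747623 to 48747838 (median score 21.1), chromosome 1, 9961797 to 9962176 (20.8), and chromosome 7, 135730756 to 135731377 (20.8). The 83 regions missing from VCaP16 were led by those on chromosomes 7, 15 and 10 named above, with median scores over the 6 libraries of 26.6, 28.7 and 22.4. With the 50% overlap only 1 of the 10 best-ranked of these, the one on chromosome 7, kept the pattern, against 8 of the 10 VCaP16 regions, from which the one on chromosome 7 dropped out. No region passed Fisher's exact test of 3 against 6 libraries after Benjamini-Hochberg adjustment over 66108 regions: the smallest p such a test can give is 0.0119, 1542 regions had an unadjusted p below 0.05, and the smallest adjusted p was 1.0. With lists of equal length the counts were 377 and 187. Without VCaP16 replicate 3 they were 801 and 321, and without VCaP16 replicates 1 or 2 they were 1339 and 153 or 1319 and 160.

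Some regions were called with short exposure and in the resistant line alike. Of the 619 regions called in VCaP_ENZ and not VCaP_DMSO, 214 (34.6%) were called in all 3 VCaP16 libraries and 96 in none. Of the 528 regions called in VCaP_DMSO and not VCaP_ENZ, 152 (28.8%) were called in no VCaP16 library and 101 in all 3. The order of 214 and 152 turned with lists of equal length, to 156 shared and 234 absent. It also turned with a score of at least 10 in the calling libraries, to 5 and 17. The 50% overlap turned it to 171 and 178. Without VCaP_DMSO replicate 3 it turned to 385 and 395, and without VCaP16 replicate 3 to 233 and 250. Without both of the longest lists the counts were 312 and 420. The order held with each other single library left out, as at 534 and 333 without VCaP_DMSO replicate 1. Examples of the second kind are the regions on chromosome 3, 161304499 to 161305074, and chromosome 5, 57994823 to 57995615. Lists drawn independently would share 14.4 and 4.03 regions. Both comparisons use the same VCaP_DMSO libraries, and simulated libraries without group effects shared 90.2 regions on average in the first case (at most 117) and 16.0 in the second (at most 29). Of the 84 choices of 3 libraries, 6 gave at least 152 regions called in those 3 and in none of the other 6, the real choice included; 1 of these is the VCaP16 group itself, with 520, and 4 mix libraries of different groups, with at most 239. Of the 1543 regions called in VCaP16 and not VCaP_DMSO, 520 were called in no VCaP_ENZ library, 463 in 1, 346 in 2 and 214 in 3.

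By chromosome, the regions called in VCaP16 and not VCaP_DMSO made up 3.05% of the consensus regions on chromosome X and 3.0% on chromosome 14, and 1.1% on chromosome 19, 1.41% on chromosome 17 and 1.48% on chromosome 22. The shares differed between chromosomes (chi-square test, p = 0.000605), which treats regions as independent. Among the regions not called in all 9 libraries the shares did not differ beyond chance (chi-square p = 0.238), nor did the spread over chromosomes differ between the VCaP16 and VCaP_DMSO directions (chi-square p = 0.89). In the same chi-square test, shares did not differ beyond chance for regions called in VCaP_DMSO and not VCaP16 (p = 0.993), in VCaP_ENZ and not VCaP_DMSO (p = 0.0775, and 0.0336 with lists of equal length) or the reverse (p = 0.417). The share of each library's peaks on chromosome 9 was 4.65% ± 0.0148 in VCaP16 (SD, n = 3) and 4.59% ± 0.0305 in the 6 VCaP libraries (exact permutation p = 0.0119, 0.274 after Benjamini-Hochberg adjustment over 23 chromosomes), and no chromosome passed the adjustment.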

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

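Across 623 recomputed values, 491 kept their direction and their side of the threshold or moved by less than 1.5 times (counts) or the replicate spread, 126 moved further, 4 turned in sign and 2 passed a threshold that the reported value missed. Each count was judged alone, so a balance that turned between opposite directions is not among the 4. Regions called in every library of a group always enter the consensus. Their counts with all merged regions therefore stayed the same by construction. The minimum score in the calling libraries, the removal of both of the longest lists and the windows about midpoints were chosen after seeing the data. Except where given, the cause was not tested. The similarity of libraries within groups stayed past its threshold under every setting run, with a difference of 0.0113 to 0.0214 when single libraries were left out. With lists of equal length, regions called in VCaP_DMSO and not VCaP16 went to 877, in VCaP_ENZ and not VCaP16 to 660, in every VCaP library and no VCaP16 library to 187, and in VCaP_DMSO but neither VCaP_ENZ nor VCaP16 to 234, while those shared by VCaP_ENZ and VCaP16 and absent from VCaP_DMSO went to 156; VCaP16 replicate 3 loses the most peaks under this setting. The chi-square over chromosomes for regions called in VCaP_ENZ and not VCaP_DMSO went to 35.6 (p = 0.0336) with lists of equal length. Of the 80 named entries, 47 kept their pattern with an overlap of at least 50% of the region. By list of 10 these were 4 for VCaP_ENZ and not VCaP_DMSO and 7 for the reverse, 8 and 9 for VCaP16 and VCaP_DMSO, 5 and 5 for VCaP16 and VCaP_ENZ, and 8 for VCaP16 and no VCaP library but 1 for the reverse. Lists of equal length cannot remove such well-ranked calls or add new ones.

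A call in at least 2 of 3 libraries admits more regions by construction. It gave 2746 regions for VCaP_ENZ and not VCaP_DMSO and 2264 for the reverse, 5208 and 1979 for VCaP16 and VCaP_DMSO, 4349 and 1869 for VCaP16 and VCaP_ENZ, 2419 and 845 for VCaP16 and all VCaP libraries, 1246 shared by VCaP_ENZ and VCaP16, and 802 absent from both. A score of at least 5 in the calling libraries gave 247 and 248, 888 and 250, 586 and 134, 268 and 29, 89, and 73 in the same order, and a score of at least 10 gave 23 and 52, 185 and 48, 115 and 7, 53 and 2, 5, and 17. Without VCaP16 replicate 3 and VCaP_ENZ replicate 2 together, the counts were 1013 and 1349 for VCaP_ENZ and VCaP_DMSO, 1224 for VCaP_DMSO and not VCaP16, 3030 and 1639 for VCaP16 and VCaP_ENZ, 1092 and 368 for VCaP16 and all VCaP libraries, and 420 absent from both drug groups.

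Leaving out a library of a compared group relaxes the rule by 1 library, and those counts rose; leaving out one of another group changes only the consensus, and 1543 went to as few as 1541 and 1068 to 1065. The ranges were 619 to 1528 for VCaP_ENZ and not VCaP_DMSO, 528 to 1341 for the reverse, 1541 to 3127 for VCaP16 and not VCaP_DMSO, 504 to 1219 for the reverse, 1065 to 2465 for VCaP16 and not VCaP_ENZ, 389 to 1122 for the reverse, 595 to 1339 for VCaP16 and no VCaP library, 98 to 321 for the reverse, 233 to 534 for regions shared by VCaP_ENZ and VCaP16, and 177 to 395 for those absent from both. The peak number differed by -1572 to 2478 between VCaP_ENZ and VCaP_DMSO and by 1662 to 7465 between VCaP16 and the VCaP libraries, and the covered length by -2.45 to 0.85 Mb between VCaP_ENZ and VCaP_DMSO. VCaP16 replicates 1, 2 and 3 covered 28.2, 29.2 and 36.4 Mb against a mean of 28.5 Mb in the VCaP libraries. The higher VCaP16 mean of 31.3 Mb thus rests largely on replicate 3.

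With the replicate number as a block, the differences in peak number stayed at 1063 (VCaP_ENZ against VCaP_DMSO, p = 1.0), 5966 (VCaP16 against VCaP_DMSO, p = 0.25), 4902 (VCaP16 against VCaP_ENZ, p = 0.75) and 5434 (VCaP16 against all VCaP libraries, p = 0.148) in exact permutation tests, and those in covered length had p values of 0.75, 0.75, 0.75 and 0.407. The block changed no call. For pairs of groups it could not, since the smallest p of the exact permutation test within this block is 0.25. Same-numbered libraries of different groups did not deviate together: their correlations over regions ran from -0.028 to 0.00788, and 0 of 9 libraries correlated best with their own number. Depth is unknown and the lists hold no value under the peak caller's limit, so how far under it a region lay where it was not called is unknown. Promoter shares, gene lists, motifs, windows about summits and the estimate of depth were planned and not run.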

Other observations

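The tests on 5 Mb stretches over splits and the comparison of control choices were chosen after their results were seen, and the counts of regions over splits were planned but what they would show was written down after; the tests with lists of equal length, of pairs of libraries, of high scores, of simulated overlaps and of neighbouring stretches were written down before. Over 5 Mb stretches of the genome with at least 30 consensus regions, the share of regions called in each library was compared after subtracting that library's average. Of 560 stretches, 24 were called less in all VCaP16 libraries than in any VCaP library and 22 more, where chance alone would give 13.3 in all. Among these, the lowest in VCaP16 were on chromosome 5 from 100 to 105 Mb (VCaP16 minus VCaP, -15.0 percentage points), chromosome 1 from 235 to 240 Mb (-13.0 points) and chromosome 7 from 60 to 65 Mb (-11.9 points). The highest were on chromosome 4 from 160 to 165 Mb (16.9 points above), chromosome 2 from 185 to 190 Mb (15.7) and from 140 to 145 Mb (14.2), chromosome 18 from 35 to 40 Mb (12.8) and chromosome X from 30 to 35 Mb (12.6). These highest stretches held only 31 to 43 regions each. The VCaP libraries called all of them poorly, with mean deviations of -25.9 to -10.1 points. The lowest stretch, on chromosome 5, held 32 regions, with an SD of 9.99 points over the VCaP16 libraries. Chromosome 5 held 5 of the 24 lower stretches, among 35 stretches in all, and chromosome 1 held 4 among 46. This spread was not tested. The most regions called in VCaP16 and not VCaP_DMSO in any Mb was 6, on chromosome 20 from 49 to 50 Mb, no more than shuffled positions often gave (permutation p = 0.46).

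Of the 84 splits into 3 and 6 libraries, 1, the real one, gave as many as these 46 stretches, and the highest other gave 37, for the 3 VCaP_DMSO libraries. The number was 32 with windows about midpoints (highest other split 29), but 35 with an overlap of at least 50% of the region and 30 with all merged regions, where another split gave 44 and 32. Without VCaP16 replicates 1, 2 or 3 it was 81, 103 or 80 (other splits at most 65, 68 and 68), and without VCaP_ENZ replicate 1 it was 50, where another split gave 59. With lists of equal length 41 stretches stood apart, 14 lower and 27 higher in VCaP16, so the balance of directions depends on this setting. The 41 lay above the 29 of the highest other split, which argues against list length as the whole cause of the number. Only 15 of the 46 stood apart in the same direction in both settings, and 2 of the 46 were not compared with lists of equal length. Single stretches therefore depend on list length. Segments of changed copy number longer than 5 Mb, which might arise in a line under long selection, would place such stretches side by side. Seen were 3 neighbouring pairs against 1.69 with shuffled positions (permutation p = 0.234), which leaves copy number open. The pairs lay on chromosome 5 from 130 to 145 Mb, as a single run, and on chromosome 8 from 110 to 120 Mb. A difference between the resistant line and VCaP cells in open chromatin stays open as well.

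More regions were called in VCaP16 and not VCaP_DMSO than in the reverse direction. With lists of equal length the ratio fell from 3.06 to 1.24, under the 1.44 that another split of the 6 libraries reached. Longer VCaP16 lists may account for the imbalance, but this setting cannot decide it. It draws the ratio toward 1 also where a real gain of open regions made the lists longer. Simulated libraries with the real yields and no group effect gave a ratio of 6.95. VCaP16 replicate 3 has the longest list, and with 2 against 2 libraries and without it the ratios were 1.21, 1.28 and 1.64. This rule is looser than that behind the 3.06, and no such ratio that keeps replicate 3 is given. These ratios alone therefore cannot separate the library from the rule. With all VCaP_DMSO libraries kept, the ratio was 1.69 without VCaP16 replicate 3, and 4.31 and 4.23 without replicates 1 and 2. Much of the imbalance may thus come from replicate 3. Calls near the peak caller's limit do not account for it alone, since 185 regions had a score of at least 10 in all 3 VCaP16 libraries, against at most 32 in other splits. The reverse direction had 48, which also lies above 32, and 3 other counts at this score lay below other splits: 23 against 38 for VCaP_ENZ and not VCaP_DMSO, 7 against 47 for VCaP_ENZ and not VCaP16, and 2 against 8 for every VCaP library and no VCaP16 library. Scores move with depth, which is unknown, so a cut on the score does not remove a difference in depth. The total in both directions, 2047 against 752.5 in simulated libraries, is separate from this imbalance. A biological difference between VCaP16 and VCaP_DMSO, from the line or the drug, stays open.

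The regions shared by VCaP_ENZ and VCaP16 and absent from VCaP_DMSO numbered 214. Of the 84 choices of 3 libraries as controls, 1, the real one, gave as many regions called in the other 6 and not in these 3. The highest other gave 151. A chance choice of controls is thus unlikely for these, but it is not excluded, since this test was chosen after its result was seen. For the 152 regions called in VCaP_DMSO and in neither drug group, 6 of the 84 choices gave as many. The highest other, 520, is the VCaP16 group itself and no chance value; 4 of the 6 mix libraries of different groups, with at most 239 regions, and all 4 include VCaP16 replicate 3, the longest list. The overlap of 214 also lies above the largest of the simulated overlaps with shared controls, 117. The bound set before the test would have read this as excluding the shared controls, but that bound was wrong, since the simulation holds no group effects and 3 controls cannot be split into parts of at least 2 libraries. Part of the excess may therefore come from the shared VCaP_DMSO libraries. A response common to short exposure and resistance is a hypothesis that these lists leave open. Since VCaP16 was also kept in the drug, they cannot tell it from the mere presence of the drug.

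For VCaP16 against all 6 VCaP libraries, 603 regions were called on one side only. Of the 84 splits 1, the real one, gave as many, and the highest other gave 366. This other split is VCaP_DMSO against the 6 libraries given the drug, a real grouping and no chance value. The total rests on the 520 regions of VCaP16. The 83 of the reverse lay below the 214 of the VCaP_DMSO split and below the 151 that the remaining splits reached at most. A chance division of the libraries is thus unlikely but not excluded, since this reading was written down after the counts were seen. The splits of 3 against 3 are too few for a share under 0.05: the real totals and the highest others were 1147 and 702 for VCaP_ENZ and VCaP_DMSO, 2047 and 743 for VCaP16 and VCaP_DMSO, and 1457 and 936 for VCaP16 and VCaP_ENZ, with 1 split of 10, the real one, as large in each case.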
